A study of Mus musculus with 20 samples.

How the data were processed

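The pool was followed in 20 libraries of mouse MLL-AF9 leukaemic cells, 2 for each of 5 days (2, 4, 8, 10 and 14) in I-BET sensitive and I-BET resistant cells. Per the labels' protocols, cells were transduced at a multiplicity of infection of 0.3, puromycin selection began at 30 h, the medium held 10 ng/ml IL-3, the resistant cells were kept in 1000 nM I-BET, and the shRNA inserts were amplified by PCR from genomic DNA. The titles of the sensitive libraries name DMSO. Libraries were grouped by line and day from their titles.

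The authors deposited a table of raw counts of sequencing reads per shRNA, with a column per library, and a list that gives the sequence and target name of each shRNA, per the file headers. The submitters' processing notes name bcl2fastq 2, edgeR and the mouse genome build mm10 (GRCm38). The rule that matched reads to shRNAs, the mismatches allowed and any filter are not given in the sources used here. Reads carried no molecular identifiers, so a count holds PCR copies, and intervals and floors cover counting error only. Totals ran from 8862425 to 32144015 counts. The list holds 271 target names, or 270 after removal of a stray space. Of these, 261 symbols matched a RefSeq gene table of GRCm38.p6, 25 of them through a synonym, 2 names matched none, and the rest were taken as controls from their names, which the files do not define. Coordinates come from that table. The positions of the shRNAs within transcripts were not determined, since no transcript sequences were used here.

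Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr at a minimum count of 10, robust dispersion and quasi-likelihood estimates, a mean for each of the 10 groups and 10 residual degrees of freedom (common dispersion 0.178). The filter kept 1720 shRNAs and left out 191, of which 179 had 0 counts in all libraries. An shRNA was called at a Benjamini-Hochberg adjusted p under 0.05. The standard error (SE) of its change was taken as the absolute log2 change over the square root of edgeR's F statistic. It is approximate, and its spread is pooled over all 20 libraries. A gene with at least 3 tested shRNAs was called when fry (limma 3.58.1) gave an adjusted p under 0.05 over genes and at least 2 of its shRNAs were called the same way. Fry tests whether the shRNAs of a set move on balance in 1 direction and does not compare the set with other shRNAs, so camera, with a preset and with an estimated correlation, and 100000 random sets of shRNAs per gene size were run beside it. Gene labels were shuffled over the shRNAs 100 times for counts of called genes and 1000 times for the share of variance between genes. Abundances (CPM) are TMM-scaled. A count of 0 was held at a floor of 3 counts per library where a bound is given, and shares of counts have Wilson 95% intervals.

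The comparisons, tests, gene lists and alternatives were fixed before the data were examined. They were day 14 against day 2 in each line, the difference between these changes, resistant against sensitive cells at day 2, and days 4, 8 and 10 against day 2. The rule for named genes took, per line, the 12 called lost genes with the lowest and the 6 called gained genes with the highest median log2 fold change, and up to 8 called genes each way for the difference. It added Kat7, the members in the pool of the HBO1 complex, MLL cofactor, PRC2, oncogene and control lists, and the lowest and highest member of every other list. For shRNAs it took those of Kat7 and the 3 with the largest change each way among those called. Some items taken by these rules are not reported here. Other genes named in the text were chosen as examples after their values were seen.

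Alternatives fixed in advance were library size without TMM, no filter, a mean of at least 100 counts, the replicate number as a block, no robust estimation, and DESeq2 1.42.0. They also included limma voom with quality weights, a slope per day, only the day 2 and day 14 libraries, camera, fry alone, at least 2 shRNAs per gene, and each of the 20 libraries left out in turn. Scaling to 7 control shRNAs, random sets and a fit without the shRNA Nons were chosen after seeing the data. So was the fit without the sensitive libraries of replicate 1. Figures were drawn with matplotlib 3.10.9.

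Replicates of a group were compared by a chi-square test of their counts, which gave 247 to 1635 per degree of freedom, so none was a copy or a second sequencing of the same library. Repeat PCRs of 1 DNA sample stay possible. The SD of the log2 difference between the replicates of a group was 0.59 to 1.02 at days 2 and 4 and 1.15 to 1.43 from day 8. The procedure was tested on simulated counts of 1717 shRNAs of 261 genes. Each shRNA had its mean over all 20 libraries, and its dispersion was the same at every day. Library depths were those of the data. Changes were placed in the sensitive day 14 libraries, in 10 genes of each size, whose changed shRNAs moved alike. The procedure recovered 72% of the shRNAs simulated at a log2 change of -2, 40% at -1, 44% at 1 and 89.8% at 2. Of the genes it recovered 100, 50, 80 and 100% at these sizes. Of 129 shRNA calls 6 were false, as were 0 of 33 gene calls, and a simulated comparison without change gave 0 calls. The real comparison of sensitive day 14 with day 2 held 766 shRNA calls. Its replicates also spread more at day 14 than at day 2, so these rates need not hold there.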

Results

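The screen followed a pool of 1911 short hairpin RNAs (shRNAs) in mouse MLL-AF9 leukaemic cells, which are haematopoietic progenitors that carry a fusion oncogene of acute leukaemia. The 270 targets named in the pool included chromatin regulators, ubiquitin and SUMO enzymes and factors of DNA replication. The cells were either sensitive or resistant to I-BET, an inhibitor of BET bromodomain proteins, and the resistant cells were kept in 1000 nM I-BET throughout. Genomic DNA was taken 2, 4, 8, 10 and 14 days after transduction, and the amplified shRNA inserts were counted, with 2 libraries for each of the 10 groups of line and day. Library totals ran from 8862425 to 32144015 counts, and the median count of a tested shRNA ran from 3056.5 to 10009.5 across the 20 libraries. Of the 1911 shRNAs, 179 had no count in any library, and 1720 entered the tests, which covered 261 genes with at least 3 shRNAs. An shRNA is called lost when its TMM-scaled abundance fell from day 2 at an adjusted p under 0.05, and gained when it rose. TMM-scaled abundance differs from the plain share of the counts. All changes are relative to the rest of the pool, and nothing in the labels says that the 2 libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

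The comparison of day 14 with day 2 asked which targets the I-BET sensitive cells needed to keep their place in the pool. The deepest losses hit genes of chromosome structure, chromatin remodelling and DNA replication. For Smc2, a core subunit of condensin (chromosome 4, 52439221 to 52488365 in GRCm38), 7 of 9 shRNAs were lost and 1 was gained, and the median log2 fold change over its shRNAs was -3.59 (SD 2.57 over 9 shRNAs). Chd4, the helicase of the NuRD remodelling complex (chromosome 6, 125095980 to 125130591), had 5 of 6 shRNAs lost and a median of -3.33 (SD 1.29 over 6 shRNAs). Sae1, a subunit of the SUMO-activating enzyme, had a median of -2.12 with 6 of 9 lost. The replicative helicase subunits Mcm4 and Mcm7 had medians of -3.28 and -3.04, with 3 of 7 and 4 of 5 shRNAs lost. Ruvbl1, an ATPase shared by several remodelling and acetyltransferase complexes, had a median of -3.04 with 5 of 7 lost, and Exosc10, a nuclease of the nuclear RNA exosome, had a median of -2.28 with 6 of 7 lost. In the other direction, all 6 shRNAs against the histone acetyltransferase Crebbp (chromosome 16, 4081334 to 4213957) were gained, with a median of 1.30 (SD 0.59 over 6 shRNAs). The next largest gains by median were Hdac6 at 1.11, the histone demethylase Kdm6a at 1.06, the Hippo pathway kinase Stk4 at 0.82, the deacylase Sirt5 at 0.78 and Tnip3 at 0.74. Gained shRNAs numbered 4 of 7 for Hdac6, 4 of 5 for Kdm6a, 5 of 8 for Stk4, 4 of 7 for Sirt5 and 3 of 8 for Tnip3 (SD 2.12). Hdac6, Sirt5 and Tnip3 each also had 1 shRNA lost. The adjusted p of these 13 genes in fry, a directional set test on the edgeR fit, lay between 1.1e-05 for Crebbp and 0.0359 for Tnip3. Of the shRNAs taken as controls from their names, Nons68 was gained by 0.79 and Nons62 by 0.66, close to the smaller of these gains.

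Among the gene groups fixed in advance, SWI/SNF subunits were lost in the sensitive cells. Of 9 tested subunits, 6 were called lost both over all genes and adjusted over the list alone, namely Smarcc1 with a median of -3.21, Smarcd2 at -2.89, Smarca4, its ATPase, at -2.81, Smarce1 at -2.30, Smarcc2 at -1.09 and Smarcb1 at -0.94. Over all genes 0 subunits were gained, and 1 was gained adjusted over the list alone. The 60 SWI/SNF shRNAs had a median of -1.56 with a fry adjusted p of 1.5e-05, a camera adjusted p of 0.00733 and adjusted p = 0.185 with an estimated correlation. Of the 9 tested genes of other MYST acetyltransferase complexes, 7 were lost in both counts, among them Ruvbl1, Ep400 at -1.64, Ruvbl2 at -1.51 and the scaffold Trrap at -1.38 (fry adjusted p = 0.000141, and adjusted p = 0.28 with an estimated correlation). The list of other histone acetyltransferases moved the opposite way, with 5 of 11 genes gained and Taf1 lost (2 lost adjusted over the list alone, fry adjusted p = 0.000298, and adjusted p = 0.185 with an estimated correlation). The call of Taf1 ended without replicate 1 of sensitive day 2 (median 0.00) or of sensitive day 14, among other settings. The gained members of the list were Crebbp, its paralogue Ep300 at 0.68, Ncoa1 at 0.64, Kat2a at 0.27 and Kat2b at 0.26. The Polycomb lists were also called gained, with 2 of 2 tested genes of the PRC2 list (Jarid2 at 0.71 and Ezh1 at 0.57, fry adjusted p = 0.00059). The PRC2 list test covered 9 shRNAs, 6 gained and 1 lost. Some of these target a further gene with too few shRNAs for a gene test. Of the PRC1 list 1 of 2 genes was gained (Rnf2 at 0.36, fry adjusted p = 0.00129), and the counts of both lists were equal adjusted over the list alone. With an estimated correlation both Polycomb lists had adjusted p = 0.312. Arginine methyltransferases had 4 of 9 genes lost (5 adjusted over the list alone) and Prmt8 gained (fry adjusted p = 0.000693, and adjusted p = 0.555 with an estimated correlation).

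Members of the remaining lists moved both ways in the sensitive cells. Among 15 other remodellers, Chd4, Chd3 at -1.27 and 3 more were lost while Chd9, Chd7 and Chd5 were gained, and the list was called lost by fry (adjusted p = 0.0223, 0.949 with an estimated correlation) although its median was 0.04. The DNA methylation list, with Dnmt1 lost at -2.08 (6 of 7 shRNAs) and Dnmt3a gained at 0.44 among 8 genes, was likewise called lost by fry (adjusted p = 0.0388, 0.949 with an estimated correlation) at a median of 0.01. The call of Dnmt3a ended without sensitive day 14 replicate 2 (median -0.04, fry adjusted p = 0.184), without sensitive day 2 replicate 2 and with library totals, among other settings. In the list of 8 genes of histone H3 lysine 9 methylation, Ehmt1 was lost at -1.82 and Ehmt2 at -0.76, while Setdb2 and Suv39h2 were gained (3 gained adjusted over the list alone, fry adjusted p = 0.0223, 0.949 with an estimated correlation). The list of 29 SET and PRDM domain genes was called gained by fry (adjusted p = 0.000176, and adjusted p = 0.185 with an estimated correlation), with 6 genes gained and 2 lost (1 lost adjusted over the list alone). Its median was 0.11 and its mean -0.23, and the median turned to -0.12 when libraries were scaled by their totals alone. COMPASS methyltransferases (3 of 9 genes lost, 3 gained), histone deacetylases and corepressors (5 of 21 lost, 6 gained) and histone demethylases (5 of 24 lost, 4 gained) passed no list test, with fry adjusted p of 0.072, 0.462 and 0.278. Under scaling by library totals the deacetylase list was called (median -0.13, fry adjusted p = 0.0267). With adjustment over the list alone these counts differed only for COMPASS, where 4 genes were lost. The counts of the remodeller and DNA methylation lists were equal adjusted over the list alone. With an estimated correlation camera called 0 lists, against 12 by fry and 1 by camera with its preset correlation. These counts leave out the list of control shRNAs. Under scaling to the 7 shRNAs taken as controls, fry called 1 list, that of Kat7, in the sensitive cells and 3 of 9 in the resistant cells (Kat7, other MYST acetyltransferase complexes and SWI/SNF).

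Over the whole pool, edgeR's quasi-likelihood test called 420 of 1720 shRNAs lost and 346 gained in the sensitive cells at day 14, and each called shRNA had both day 14 libraries on the same side of both day 2 libraries. The calls rest on these same libraries, so this order is no separate support for them. Chance alone puts 16.7% of all shRNAs in such an order in each direction, and the share over all 1720 was not counted. A change of at least 4-fold was reached by 163 lost and 9 gained shRNAs. At the gene level 72 of 261 genes were lost and 52 gained. Shuffling the gene labels over the shRNAs 100 times gave a mean of 67.2 lost (57 to 81) and 40.5 gained genes (27 to 57). Of these shuffles 17 called at least 72 genes lost and 1 at least 52 gained. Against other shRNAs, as camera with its preset correlation tests it, 7 genes were lost (Smc2, Smarcc1, Exosc10, Aurkb, Rfc1, Smc3 and Rnf20) and 3 gained (Stk4, Kdm6a and Crebbp). An estimated correlation left 0, with a lowest adjusted p of 0.417 and 150 genes at an unadjusted fry p under 0.05. Scaling by library totals alone moved the split of called shRNAs from 54.8% lost to 71.4% lost and left 11 genes gained, and scaling to the 7 shRNAs taken as controls from their names, Nons among them, left 23 genes lost and 1 gained.

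**Figure D1:**
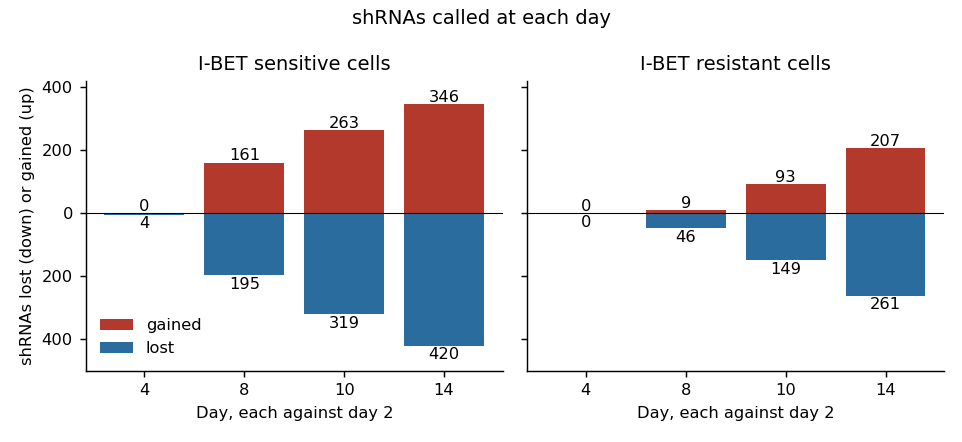
Bars give the number of shRNAs called gained (upward) or lost (downward) at days 4, 8, 10 and 14 against day 2 of the same line, out of 1720 tested, in sensitive cells (left) and resistant cells (right), with 2 libraries per day. Calls rose from 4 at day 4 to 420 lost and 346 gained at day 14 in the sensitive cells, and from 0 to 261 lost and 207 gained in the resistant cells.

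In the resistant cells, kept in I-BET, the deepest losses were those of the chromatin ATPases Ruvbl1, Chd4 and Smarca4, while another, Chd7, was gained. Ruvbl1 (chromosome 6, 88465409 to 88497566) had a median of -5.13 over 7 shRNAs, or -4.06 when its 2 shRNAs without any count at day 14 were held at a floor of 3 counts per library, and 3 of its shRNAs were called lost. Chd4 had a median of -2.50 and Smarca4 of -2.27, each with 3 of 6 shRNAs lost. The mitotic kinase Aurkb lost 7 of 8 shRNAs at a median of -2.21 (SD 0.62 over 8 shRNAs), Exosc10 lost 7 of 7 at -1.96, and the histone H2B ubiquitin ligase Rnf20 lost 5 of 8 at -2.10. Trrap at -2.15, Smarcc1 at -2.13, Smc2 at -2.03, Mcm4 at -2.01, Smarcd2 at -1.94 and the condensin subunit Smc4 at -1.92 completed the 12 largest losses. The largest gains belonged to the ubiquitin-conjugating enzyme Ube2e1 with a median of 1.46 (4 of 5 shRNAs gained) and the chromatin helicase Chd7 at 1.44 (6 of 7), followed by Kdm5c at 0.91, Crebbp at 0.88, Kdm6a at 0.77 and Stk4 at 0.77. Among these 18 genes the fry adjusted p ran from 5.8e-05 for Aurkb to 0.0422 for Mcm4. Nons68, an shRNA taken as a control from its name, was gained by 0.77, as much as the medians of Kdm6a and Stk4.

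The same 6 of 9 SWI/SNF subunits were lost in the resistant cells, over all genes and adjusted over the list alone. The list had a median of -1.06, a fry adjusted p of 4.7e-05, a camera adjusted p of 0.00213 and adjusted p = 0.0571 with an estimated correlation. Other MYST acetyltransferase complexes had 5 of 9 genes lost in both counts (Ruvbl1, Trrap, Ep400 at -1.88, Ruvbl2 at -1.19 and Dmap1 at -0.32), with a fry adjusted p of 2.6e-05, a camera adjusted p of 0.000499 and adjusted p = 0.0571 with an estimated correlation. None of these 5 is a MYST acetyltransferase itself, so the call of the list does not show a need for its acetyltransferases. Both tested PRC1 genes, Rnf2 at 0.74 and Ring1 at 0.50, were gained (fry adjusted p = 0.000527, and adjusted p = 0.135 with an estimated correlation). The PRC2 list was called gained as well (fry adjusted p = 0.0226, and adjusted p = 0.449 with an estimated correlation) with 1 of 2 tested genes gained, Jarid2 at 0.51, and Ezh1 not called at -0.05 (fry adjusted p = 0.879). The test turned to the other side at a median of 0.04 under scaling to the control shRNAs. Of other histone acetyltransferases 4 of 11 genes were gained and 0 lost (fry adjusted p = 0.00219, and adjusted p = 0.135 with an estimated correlation). The median of this list was 0.07 and its mean -0.04, and the median turned to -0.14 and -0.23 under scaling by library totals and to the control shRNAs. COMPASS genes were called lost as a list (2 of 9 lost, 1 gained, fry adjusted p = 0.00188, and adjusted p = 0.591 with an estimated correlation), among them Kmt2b, named Wbp7 in the pool, at -1.41. Arginine methyltransferases were too, with Prmt1 at -1.01 and Carm1 at -0.98 (fry adjusted p = 0.0134, and adjusted p = 0.687 with an estimated correlation). Other remodellers (4 of 15 genes lost, 3 gained), histone deacetylases and corepressors (4 of 21 lost, 3 gained) and histone H3 lysine 9 methylation genes (2 of 8 lost, 1 gained) passed no list test, with fry adjusted p of 0.968, 0.0578 and 0.0615. Neither did SET and PRDM domain genes (4 of 29 lost, 1 gained), demethylases (3 of 24 lost, 6 gained) and DNA methylation genes (1 of 8 lost, 0 gained), with fry adjusted p of 0.346, 0.0846 and 0.175. Adjusted over the list alone, 2 SET and PRDM genes were lost and 5 demethylases gained, and the other counts of these lists were equal.

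In all, 261 shRNAs were lost and 207 gained in the resistant cells at day 14, and 88 and 6 of them changed at least 4-fold. Each again showed no overlap between the day 14 and day 2 libraries, on which the calls themselves rest. The 53 lost and 36 gained genes exceeded those of every one of 100 shuffles of the gene labels, which gave means of 38.1 lost (26 to 47) and 18.0 gained (10 to 29). Camera with its preset correlation called 10 genes lost and 5 gained, among them Aurkb and Chd7, and with an estimated correlation called 0, with a lowest adjusted p of 0.202 and 119 genes at an unadjusted fry p under 0.05. Scaling by library totals moved the split of called shRNAs from 55.8% to 79.5% lost, and scaling to the control shRNAs to 94.8%. Gained genes then numbered 8 and 1, and lost genes fell to 33 with the control shRNAs. The day 2 and day 14 libraries alone gave 20 gained genes. Without the resistant day 2 library of replicate 2 the calls fell to 154 lost and 102 gained shRNAs and to 30 lost and 15 gained genes, and without that of replicate 1 the gained shRNAs fell to 112 and the genes to 32 lost and 14 gained. Without resistant day 14 replicate 2, 18 genes were gained.

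The changes of the lines were compared across the pool. Of the shRNAs lost in the sensitive cells, 195 were also lost in the resistant cells, against 63.7 from independent lists of these sizes, and 140 were gained in both, against 41.6. The lines use separate day 2 libraries. One-sided Fisher's exact tests across shRNAs, which are not independent replicates, gave p = 1.6e-80 and 9.4e-59. Opposite calls were rarer, with 2 shRNAs lost in sensitive and gained in resistant cells and 5 the other way. At the gene level 43 genes were lost in both lines and 25 gained in both, and 0 were called in opposite directions. Across the 1720 shRNAs the log2 fold changes of the lines had Pearson's r = 0.571 and Spearman's rho = 0.624, and across the 261 gene medians r = 0.775 and rho = 0.679. These are correlations across shRNAs or genes, which are not independent replicates. The shared losses included Smc2, Chd4, Smarca4, Smarcc1, Ruvbl1, Exosc10, Aurkb and Dnmt1, and the shared gains Crebbp, Kdm6a, Stk4, Chd7 and Sirt5. Gene labels accounted for 17.9% of the variance between shRNAs in sensitive and 18.7% in resistant cells, above the highest of 1000 shuffles (5.16% and 5.23%), for a one-sided permutation p of 0.000999 in each line, the smallest that 1000 shuffles can give. Without resistant day 2 replicate 2, 123 shRNAs were lost and 77 gained in both lines, and without replicate 1 of that day 83 were gained in both. Scaling by library totals left 49 gained in both, and scaling to the control shRNAs 128 lost and 5 gained.

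**Figure D2:**
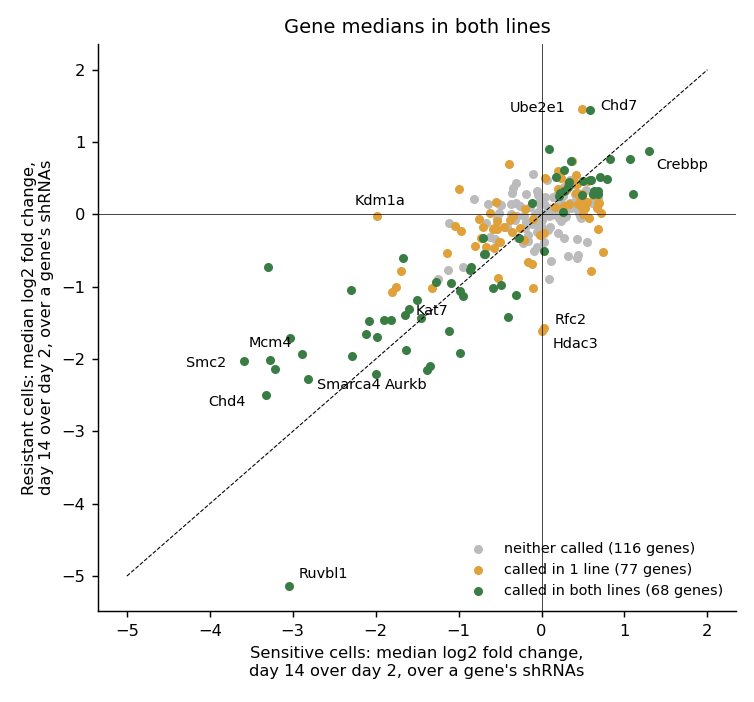
Each point is 1 of 261 genes, placed by its median log2 fold change from day 2 to day 14 over its shRNAs in sensitive cells (horizontal axis) and in resistant cells (vertical axis). The dashed line marks equal changes, colours show in how many lines a gene was called (68 in both, 77 in 1 and 116 in neither), Kdm1a lies at -1.99 and -0.02, and Ruvbl1 at -3.04 and -5.13.

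Kat7, the MYST acetyltransferase also known as HBO1, is the gene of the study's title and is named Myst2 in the pool (chromosome 11, 95271853 to 95310246 in GRCm38). It was the sole gene of the fixed HBO1 complex list found in the pool, and as a list it had a fry adjusted p of 0.00042 in sensitive and 0.00188 in resistant cells, and adjusted p = 0.312 and 0.288 with an estimated correlation. It was called lost in both lines, at a median log2 fold change of -1.64 in sensitive (SD 1.18 over 6 shRNAs, fry adjusted p = 0.0007) and -1.39 in resistant cells (SD 1.38 over 6 shRNAs, fry adjusted p = 0.00262). The shRNA Myst2.4 (GCTGATCGATTTCAGTTATTTA) fell from 1100 ± 21.1 to 197 ± 29.2 CPM (TMM-scaled) in sensitive cells and from 1104 ± 178 to 162 ± 27.9 in resistant cells (SD, n = 2), log2 changes of -2.48 (SE 0.26) and -2.77 (SE 0.26). Myst2.2 (ACGGCAAGAAGAACAAGATCTA) changed by -2.05 (SE 0.38) and -2.66 (SE 0.39), and Myst2.5 (GAAGGAAGAAGTGTTCCCTCTA) by -2.68 (SE 0.45) and -1.74 (SE 0.43). These 3 passed edgeR's test in each line, with adjusted p of at most 0.00646. Myst2.3 was called lost in sensitive cells alone (-1.24, adjusted p = 0.0347 in edgeR, against -1.05 and 0.0978 in resistant cells), and its difference between the lines did not pass the test (adjusted p = 0.911 in edgeR). Myst2.8 and Myst2.10 passed in neither line at day 14, with changes of -0.47 and 0.31 in sensitive and 0.60 and 0.02 in resistant cells, but Myst2.8 was called gained at resistant day 10 (0.78, adjusted p = 0.0263 in edgeR). In the test of the difference between the lines, Kat7 had a median of -0.05 (SD 0.70 over 6 shRNAs, fry adjusted p = 0.726), and of its shRNAs Myst2.8 alone differed, by 1.07 (SE 0.31, adjusted p = 0.0359 in edgeR). Compared with other shRNAs, Kat7 did not pass camera (adjusted p = 0.125 in sensitive and 0.0656 in resistant cells, and adjusted p = 0.727 and 0.519 with an estimated correlation), nor random sets of 6 shRNAs (adjusted p = 0.308 and 0.203). Adjusted over the fixed lists in place of all genes, the same shRNAs passed camera with its preset correlation in resistant (adjusted p = 0.0199) and not in sensitive cells (adjusted p = 0.0705).

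**Figure D3:**
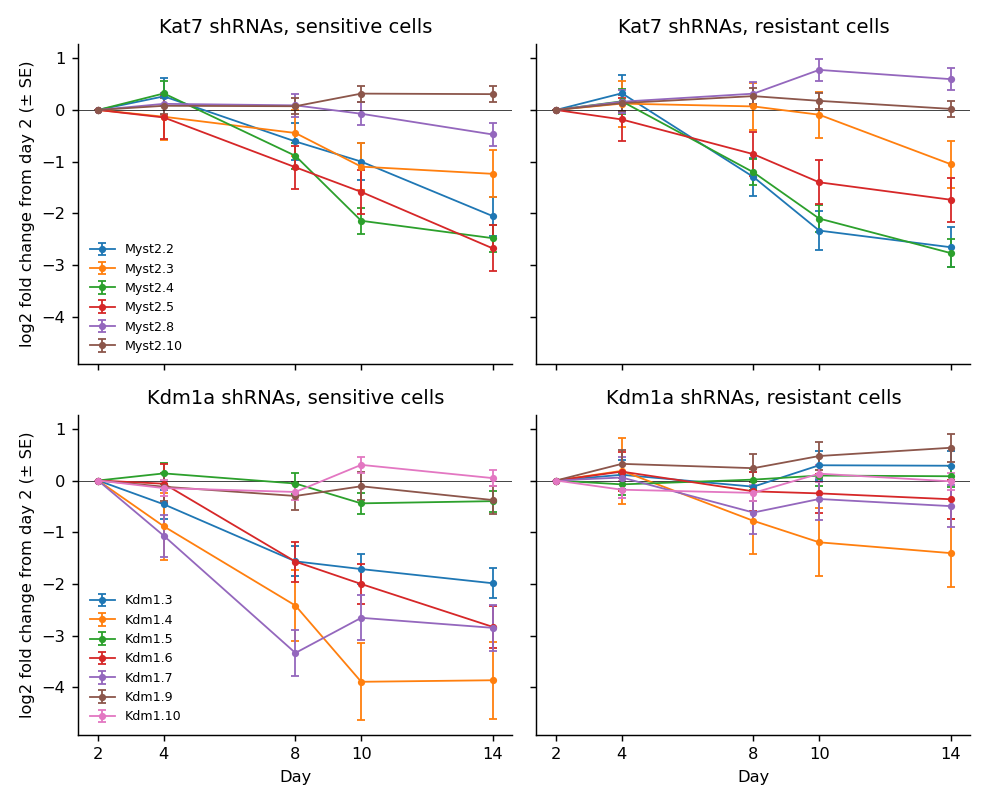
Lines give the log2 fold change of each shRNA from day 2, which is set to 0, at days 4, 8, 10 and 14, with 2 libraries per day. Kat7 is at the top and Kdm1a at the bottom, with sensitive cells on the left and resistant cells on the right. Bars are standard errors derived from edgeR's F statistic, with the spread pooled over all 20 libraries. Myst2.4 ended at -2.48 and -2.77 in the respective lines, whereas Kdm1.6 ended at -2.83 in sensitive and -0.36 in resistant cells.

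Other targets with a known link to this leukaemia were tested too. Dot1l, the histone methyltransferase recruited by MLL fusions, was the sole MLL cofactor of the fixed list found in the pool. It passed no test, with medians of -0.53 in sensitive (SD 1.22 over 5 shRNAs, fry adjusted p = 0.889) and -0.04 in resistant cells (SD 1.63 over 5 shRNAs, fry adjusted p = 0.993). As a list it had a fry adjusted p of 0.872 and 0.968. Its shRNA Dot1l.3 took 0.116 to 0.385% of the counts in the 5 sensitive libraries of replicate 1 and 0.133% (Wilson 95% interval 0.132 to 0.135) in resistant day 14 replicate 1, against 0.00487 to 0.0519% in the others, together with the shRNA Nons. Mecom, a leukaemia oncogene and the sole member of its list in the pool, was gained in both lines, at 0.60 with 6 of 8 shRNAs and 0.47 with 3 of 8. The fry adjusted p was 0.00124 and 0.00531, and as a list it had adjusted p = 0.312 and 0.288 with an estimated correlation. Its shRNA Mecom.1 reached 4.77% of the counts (Wilson 95% interval 4.76 to 4.78) in resistant day 8 replicate 1 and 1.90% (1.89 to 1.90) in sensitive day 2 replicate 1, and in these libraries Mll5.1, against Kmt2e, reached 1.62% (1.61 to 1.63) and 0.662% (0.658 to 0.666). Kmt2e, named Mll5 in the pool, was gained in sensitive cells at 0.66 (4 of 8 shRNAs, fry adjusted p = 0.00025). The fixed lists of BET genes, general essential genes and tumour suppressors matched no name in the pool, and these genes were not analysed here.

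The difference between the changes of the lines asked which targets mattered more to one line than to the other, with resistance and I-BET exposure inseparable because all resistant cells were kept in the drug. Kdm1a, the histone demethylase LSD1 (Kdm1 in the pool, chromosome 4, 136550533 to 136602787), showed the largest median difference among the called genes. It fell by 1.99 on the log2 scale in sensitive cells with 4 of 7 shRNAs lost, and had a median of -0.02 with 0 lost in resistant cells, a median difference of 2.27 (SD 1.07 over 7 shRNAs, fry adjusted p = 0.0451). Kdm1.3, Kdm1.6 and Kdm1.7 each passed edgeR's test of the difference, with differences of 2.27 (SE 0.41), 2.47 (SE 0.55) and 2.35 (SE 0.59). Further genes whose shRNAs fared better in resistant cells were the cohesin subunit Smc1a at 1.16, Smc5 at 1.12, the arginine methyltransferase Prmt5 at 0.93 and Kdm4a at 0.47 (fry adjusted p from 0.000941 to 0.0451). Those whose shRNAs fared worse were the replication factor Rfc2 at -0.98, the ubiquitin-conjugating enzyme Ube2a at -0.37 and Kat2b at -0.11 (fry adjusted p from 0.00466 to 0.0458). Of the fixed lists, the SET and PRDM domain genes alone passed fry for the difference (median -0.14, mean 0.10, adjusted p = 0.00263), and did not pass camera (adjusted p = 0.673, and adjusted p = 0.641 with an estimated correlation). Adjusted over the list alone, 1 COMPASS gene was higher and 1 deacetylase list gene lower in addition to the genes called over all.

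Of single shRNAs, 98 fared better and 72 worse in resistant cells by edgeR's test of the difference. Mll3.1, against Kmt2c, differed by 8.76 (SE 2.65), Smarce1.5 by 5.59 (SE 1.14) and Smc2.6 by 5.35 (SE 1.36), while Smyd2.4 differed by -5.80 (SE 1.55), Smg6.8 by -2.69 (SE 0.75) and Hat1.4 by -2.61 (SE 0.71). Over both libraries of a day Mll3.1 had 5 counts at day 14 against 1709 at day 2 in sensitive cells, and 1218 (77 and 1141) against 1160 in resistant cells. Over all shRNAs of the tested genes, gene labels accounted for 0.739% of the variance of the differences. This lay within the range of 1000 shuffles (one-sided permutation p = 0.31). Shuffled gene labels gave a mean of 7.77 called genes against the 8 observed, with at least 8 in 55 of 100 shuffles. Leaving out each library in turn gave 0 to 5 lower and 0 to 8 higher genes and kept the call of Kdm1a in 7 of 20 settings (fry adjusted p from 0.01 to 0.135). The shRNA counts fell to 37 lower and 37 higher without resistant day 2 replicate 1, 38 and 35 without its replicate 2. They fell to 41 and 53 without sensitive day 2 replicate 1, and 43 and 47 without its replicate 2. Scaling by library totals moved the split from 42.4% to 34.6% lower, scaling to the control shRNAs left 4 lower and 0 higher shRNAs and 0 genes. Camera with its preset correlation called Smc5 and Kdm1a, and random sets called Smarcc1 and Kdm1a.

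At day 2 the lines did not differ detectably. EdgeR's test called 0 of 1720 shRNAs between resistant and sensitive cells, while DESeq2 called 2 and limma voom 0. At an unadjusted p under 0.05 edgeR's test held 8 shRNAs, against 86 expected without any difference. The fit uses the same spread for all days, while replicates differed less at days 2 and 4 than from day 8. With so few low p-values the test was conservative here, and 0 calls do not show that the lines were equal. Without resistant day 2 replicate 2, edgeR called 2.

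Losses and gains built up with time. In the sensitive cells 4 shRNAs were called at day 4, 356 at day 8 and 582 at day 10, and in the resistant cells 0, 55 and 242. At day 4 of the resistant cells 28 shRNAs had an unadjusted p under 0.05, against 86 expected without any change. EdgeR's test was thus conservative there too, and DESeq2 called 0 and limma voom 7. Aurkb medians in sensitive cells were -0.67 at day 4, -1.97 at day 8, -2.31 at day 10 and -1.997 at day 14, and in resistant cells -0.14, -1.54, -2.23 and -2.21. Chd4 was called lost from day 8 in sensitive cells, at -1.79, and at day 14 alone in resistant cells, where its medians at days 8 and 10 were -1.50 and -2.50. Chd7 in resistant cells had medians of 0.09, 0.39, 0.72 and 1.44 at the 4 later days and was called gained from day 10. The days of a line share its day 2 libraries. The sensitive day 8 count fell to 142 without sensitive day 8 replicate 2 and to 179 or 158 without sensitive day 2 replicate 1 or 2. The sensitive day 4 count fell to 0 without either of these or sensitive day 4 replicate 2 and to 2 without sensitive day 4 replicate 1. The resistant day 8 count fell to 29 or 18 without resistant day 8 replicate 1 or 2 and to 22 without either resistant day 2 library. The resistant day 10 count fell to 161 or 84 without resistant day 10 replicate 1 or 2 and to 107 or 104 without resistant day 2 replicate 1 or 2. Without resistant day 2 replicate 2, 2 shRNAs were called at resistant day 4. Other tests called more, with 10 at sensitive day 4 and 120 at resistant day 8 in DESeq2, and 15 at sensitive day 4 and 205 and 425 at resistant days 8 and 10 in limma voom. Scaling to the control shRNAs called fewer, with 0, 83 and 211 in sensitive cells at days 4, 8 and 10 and 23 and 79 in resistant cells at days 8 and 10.

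The shRNAs taken as controls from their names gave the background. Luc, Nons60 and Nons65 passed the test in neither line, with changes of -0.47, -0.46 and -0.65 in sensitive and 0.31, -0.04 and -0.10 in resistant cells. Nons68 was gained in both, by 0.79 (SE 0.21) and 0.77 (SE 0.21), and Nons62 in sensitive cells by 0.66 (SE 0.16), against 0.22 (SE 0.16) in resistant cells. The shRNA named Nons stood apart. It took 2.69, 4.75, 7.18, 12.97 and 8.29% of the counts in the sensitive libraries of replicate 1 at days 2, 4, 8, 10 and 14, with a Wilson 95% interval of 12.95 to 12.98 at day 10. In resistant day 14 replicate 1 it took 3.12% (3.11 to 3.13), against 0.0734 to 0.211% in the other 14 libraries. These intervals cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Its change did not pass edgeR's test (1.78, SE 2.60, adjusted p = 0.614 in sensitive and 4.09, SE 2.86, adjusted p = 0.313 in resistant cells). In an alternative chosen after seeing the data, without the 5 sensitive libraries of replicate 1, 25 genes were gained in place of 52 in the sensitive cells at day 14, and 219 and 374 shRNAs were called at days 8 and 10.

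**Figure D4:**
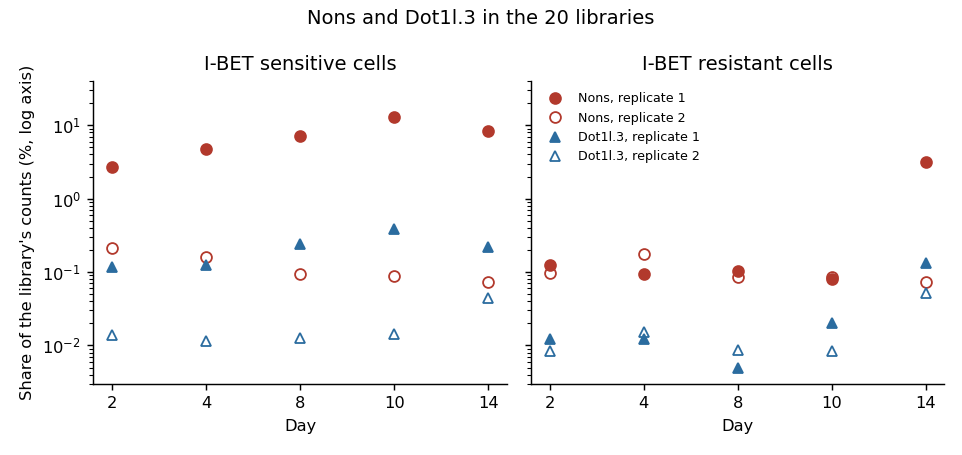
Points give the share of each library's counts taken by the shRNAs Nons (circles) and Dot1l.3 (triangles) in the 20 libraries, on a log axis in percent, by day, with filled symbols for replicate 1 and open symbols for replicate 2. In sensitive replicate 1 Nons took between 2.69 and 12.97%, and in resistant replicate 1 it stood at 0.0796% at day 10 and 3.12% at day 14.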

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

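All tests in this part were chosen after the patterns were seen. The predictions for mixed DNA, a shared outside source, cell expansion, single shRNAs, single libraries and the scale of Kdm1a were written after the results they rest on. That for the scale of the 170 differences was written before its count was known, and that for I-BET had no library to test it.

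The shRNA Nons, taken as a control from its name, took 12.97% of the counts in sensitive day 10 replicate 1 and 3.12% in resistant day 14 replicate 1, far above its share in the replicates of the same groups. In the same 6 libraries Dot1l.3 stood above its share elsewhere, as did Mll5.1 beside Mecom.1 in 3 libraries. Mixing of DNA of sensitive day 14 replicate 1 into resistant day 14 replicate 1 was tested, and the values argued against it. Nons needs a mixed share of 37.0%, while 18 other shRNAs gave a median of 3.37% (bootstrap 95% interval -17.6 to 26.8). Another library as the donor, such as sensitive day 10 replicate 1, was not tested and stays open. An outside source that holds Nons and Dot1l.3 in a fixed ratio is a candidate explanation, since the excess of Dot1l.3 over that of Nons in resistant day 14 replicate 1 was 0.904 times its mean in the sensitive replicate 1 libraries (0.0268 against 0.0296, range 0.0215 to 0.0412). That ratio did not cover every rise of Dot1l.3. In replicate 2, Dot1l.3 stood at 0.0145% at day 10 and 0.0446% at day 14 in sensitive cells. In resistant cells it stood at 0.00827% and 0.0519%. Nons took 0.0742 and 0.0734% in these day 14 libraries, which also served as baselines for the excess. For the other pair too, 1 fixed ratio did not cover every rise. Mecom.1 also stood at 1.16% in sensitive day 8 replicate 1, where Mll5.1 took 0.191%. The ratio there was 0.165, against 0.340 to 0.386 in the 3 libraries, and in sensitive day 2 replicate 2 it was 0.219 with Mecom.1 at 0.889%. Expansion of cells that carry both stays open, as Mecom.1 stood at 1.90% in sensitive day 2 replicate 1, 0.260% at day 4 and 1.16% at day 8, but no label says that these libraries follow 1 culture. No group of the design separates expansion from a technical source.

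The changes of 170 shRNAs differed between the lines by edgeR's test of the difference. Under TMM, 1 smaller scale of all changes in the resistant cells (slope 0.788, fitted to these same changes) did not account for all of them. After that scale was taken out 118 shRNAs were called, 108 of them among the 170. Under scaling to the control shRNAs the plain difference held 4 lower and 0 higher shRNAs, and the test of the scale was not run there. Over all shRNAs of the tested genes, gene labels accounted for 0.739% of the variance of the differences, within the range of shuffled labels. Changes of single shRNAs predict this, but so does noise, and the share does not tell them apart. It was not computed for the 170 shRNAs alone. Resistance and I-BET exposure stay confounded.

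The change of Kdm1a differed between the lines by a median of 2.27 on the log2 scale. After the scale of all changes in the resistant cells was taken out, a median of 1.64 remained, so that scale did not remove the difference. The middle 95% of random sets of 7 shRNAs lay at -0.59 to 0.64 (two-sided permutation p = 0.00023 over random draws of shRNAs, unadjusted for the 261 genes). Kdm1a was picked for its large difference, so its place outside this range was partly fixed by that choice. The random sets thus cannot decide whether the remainder exceeds noise. The fry adjusted p rose from 0.0451 to 0.065 and 2 of 7 shRNAs stayed called, so the gene's call ended with the smaller difference. The size of the difference did not rest on 1 library, with a lowest median of 1.75 without sensitive day 14 replicate 2. The adjusted p in fry ran from 0.01 to 0.135 with each library left out and from 0.00279 to 0.121 over the other alternatives except the estimated correlation (0.972). A weaker need for Kdm1a in resistant cells and an effect of I-BET itself cannot be told apart, because there were 0 libraries of resistant cells without I-BET.

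Other genes whose changes differed between the lines by fry were Smc1a (1.16), Smc5 (1.12), Prmt5 (0.93), Kdm4a (0.47), Kat2b (-0.11), Ube2a (-0.37) and Rfc2 (-0.98), as median log2 differences of resistant minus sensitive cells. Single shRNAs that differed by edgeR's test were Mll3.1 (8.76), Smarce1.5 (5.59), Smc2.6 (5.35), Chd7.10 (2.997), Myst2.8 (1.07), Prdm11.4 (-1.13), Hat1.4 (-2.61), Smg6.8 (-2.69) and Smyd2.4 (-5.80).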

How the results depend on the processing

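Scaling to 7 control shRNAs, random sets of shRNAs and a fit without the shRNA Nons were chosen after seeing the data. So was the fit without the sensitive libraries of replicate 1, which leaves 1 library in each sensitive group. The other alternatives were planned. Among the alternatives that keep all libraries, named genes reversed 6 times and lists 5 times, and the cause was not tested. The planned scaling to neutral controls was not run, because the fixed list matched 2 of the 3 shRNAs needed. The median change of all shRNAs was -0.25 in sensitive and -0.27 in resistant cells with library totals, 0.16 and -0.35 with the 7 controls, and -0.01 and -0.04 with TMM. The median difference was -0.48 with the controls and 0.01 with TMM, so all changes are relative to the scaling. At day 14, 26 shRNAs in sensitive and 31 in resistant cells had 0 counts in both libraries, and 1 and 4 of them were called lost. At day 2, 10 and 11 shRNAs had 0 counts in both libraries.

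With library totals alone, gained shRNAs numbered 199 in sensitive cells, 87 in resistant cells and 49 in both, gained genes 11 and 8, and the difference held 44 lower shRNAs and 1 lower gene. Medians turned to -0.23 for Hdac3 and -0.16 for Kdm5c in sensitive and -0.18 for Kat2b and -0.22 for Ube2a in resistant cells, and to -0.13 for the deacetylase list and -0.12 for the SET and PRDM list in sensitive and -0.14 for other acetyltransferases in resistant cells. Of these, Hdac3 (adjusted p = 0.0302), Ube2a and the deacetylase list were then called. With the 7 controls, 238 shRNAs were lost and 179 gained in sensitive cells, 12 gained in resistant cells, 128 lost and 5 gained in both, and 4 lower and 0 higher in the difference. The time course then gave 0, 83 and 211 calls in sensitive cells at days 4, 8 and 10 and 23 and 79 in resistant cells at days 8 and 10. Genes numbered 23 lost and 1 gained in sensitive, 33 lost and 1 gained in resistant cells and 0 each way in the difference, and lists 1 and 3. Medians turned to -0.028 for Hdac6, -0.27 for Kat2b and -0.23 for other acetyltransferases in resistant cells, and the PRC2 test turned at a median of 0.039.

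Camera with its preset correlation called 7 lost and 3 gained genes in sensitive cells, 10 and 5 in resistant cells, 0 and 2 in the difference, and 1 and 4 lists. With an estimated correlation it called 0 genes each way and 0 lists, and fry alone called 8 and 9 genes in the difference. Random sets called 6 and 1, 6 and 3, and 0 and 2 genes. The day 2 and day 14 libraries alone gave 27 lower and 42 higher shRNAs, 0 and 1 genes in the difference and 20 gained genes in resistant cells. DESeq2 called 2 shRNAs at day 2, 10 at sensitive day 4 and 120 at resistant day 8, and limma voom 15 at sensitive day 4 and 7, 205 and 425 at resistant days 4, 8 and 10. A slope per day gave 324 gained shRNAs in resistant cells and 124 lower in the difference. Without the sensitive libraries of replicate 1, 47 shRNAs and 1 gene were lower in the difference, 219 and 374 shRNAs were called at sensitive days 8 and 10 and 87 at resistant day 8. Then 25 genes were gained in sensitive cells, and Smc4 had a sensitive median of 0. Correlation of the lines across shRNAs was then 0.387, against 0.655 with a mean of at least 100 counts, 0.516 in DESeq2 and 0.641 in limma voom.

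Replicate numbers did not meet the rule for pairing, r over 0.1 in every pair, since deviations of same-numbered libraries did so in 7 of 10 pairs of sensitive groups and 4 of 10 of resistant groups. They shared some deviations within a line, with r up to 0.309 and 0.212 and a median of 0.00740 between lines. With the replicate block 97 shRNAs were called at resistant day 8, and the block moved no other count by over 1.5 times.

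With each library left out in turn, where the group's lone library is assumed to vary like the others, sensitive cells gave 329 to 431 lost and 264 to 352 gained shRNAs and 58 to 75 lost and 39 to 56 gained genes. Resistant cells gave 154 to 292 and 102 to 226 shRNAs and 30 to 54 and 14 to 40 genes. The difference gave 37 to 73 lower and 35 to 111 higher shRNAs and 0 to 5 lower and 0 to 8 higher genes, day 2 gave 0 to 2 calls, and 123 to 210 shRNAs were lost and 77 to 147 gained in both lines. The sensitive time course gave 0 to 5, 142 to 415 and 404 to 630 calls, the resistant 0 to 2, 18 to 75 and 84 to 273, and lists 10 to 13 and 7 to 12. Genes of the difference fell to 0 lower and 1 higher without sensitive day 2 replicate 1, to 1 and 1 without its replicate 2. They fell to 1 and 0 or 0 and 0 without resistant day 2 replicate 1 or 2, and to 1 and 2 without any 1 of the day 4 libraries. They numbered 5 and 8 without sensitive day 10 replicate 1, 1 lower without sensitive day 14 replicate 2, 2 higher without either resistant day 8 library and 3 higher without resistant day 14 replicate 2. Sensitive medians ran from -0.070 (without sensitive day 2 replicate 1, and -0.020 without sensitive day 14 replicate 2) to 0.31 for Kdm5c, from -1.70 to 0 (without sensitive day 2 replicate 1) for Taf1. With the lowest value without sensitive day 14 replicate 2, they ran from -0.037 to 0.72 for Dnmt3a and from -0.32 to 0.33 for Smarcd1. The resistant median of Kat2b ran from -0.0097 (without resistant day 14 replicate 2) to 0.34.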

Other observations

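The groups of genes in this part and their tests were chosen after the values were seen, so their p-values, unadjusted over the 4 groups tested, are not independent evidence. Genes of the structural maintenance of chromosomes family and the cohesin subunit Rad21 fell together in sensitive cells, where 8 of 8 genes were called lost by fry and 30 of 57 shRNAs were lost and 4 gained. Their median log2 change was -1.45 (camera p = 1.2e-06, and p = 0.00019 with an estimated correlation). Smc3 had a median of -1.90 (SD 0.99 over 8 shRNAs, 6 lost), Rad21 of -1.81 (SD 2.49 over 6 shRNAs, 3 lost and 1 gained) and Smc1a of -1.67 (SD 3.12 over 8 shRNAs, 4 lost). The weakest were Smc5 at -0.55 (3 of 6 lost), Smc1b at -0.45 (3 of 9 lost, 1 gained) and Smc6 at -0.21 (2 of 4 lost). Such calls were common in sensitive cells, with 72 of 261 genes lost and a mean of 67.2 under shuffled gene labels. In resistant cells 4 of the 8 genes, namely Smc1a, Smc2, Smc3 and Smc4, were lost, with 15 of 57 shRNAs lost and 4 gained (median -0.82, camera p = 0.00214, and p = 0.00871 with an estimated correlation). Of the 8 genes Smc1a and Smc5 passed fry for the difference between the lines.

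Both subunits of the ligase that ubiquitinates histone H2B, Rnf20 and Rnf40, were lost in both lines. Rnf40 stood at -1.11 in sensitive (4 of 8 shRNAs) and -1.61 in resistant cells (3 of 8). The conjugating enzyme Ube2a was gained in sensitive cells at 0.50 (4 of 8, fry adjusted p = 0.000244). It was not called in resistant cells (0.00, fry adjusted p = 0.168), but under scaling by library totals it was called there at a median of -0.22 (fry adjusted p = 0.0442). With Ube2b these genes as a group did not pass camera in sensitive cells (p = 0.108, and p = 0.0985 with an estimated correlation) and did in resistant cells (p = 0.000956 and 0.00378). Of 5 replication genes, 3 were lost in sensitive cells (Mcm4, Mcm7 and Rfc1) and all 5 in resistant cells, where Rfc2 had a median of -1.57 and Cdc6 of -0.78. The group passed camera in both lines (p = 0.00767 in sensitive and 1.9e-05 in resistant cells), but with an estimated correlation in resistant cells alone (p = 0.0863 and 0.0133).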
